A study of Mus musculus with 42 samples.

How the data were processed

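RNA was measured in 42 mouse (C57Bl/6J) tumour biopsies, 1 library per biopsy, taken on day 13 after tumour inoculation. Per the labels' protocols, RNA was isolated on silica columns, libraries were made with a stranded total RNA kit that removes ribosomal RNA, and they were sequenced as paired reads. The tumour line, the sex of the mice, the housing and the order of library preparation are not given in the sources used here. Per the submitters' processing notes, FastQC 0.11.9, MultiQC 1.12, Trimmomatic 0.39, Salmon 1.9.0, R 4.2.2 and DESeq2 1.36.0 were used with genome build GRCm39; the role of each and the parameters are not given in the sources used here.

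Each deposited file lists 147828 transcripts in the layout of Salmon, with the length, the effective length, TPM and the estimated number of reads of each transcript per the file headers. The deposited estimated counts, which need not be whole because Salmon shares a read between the transcripts it fits, were the values analysed; they carried no normalization. The deposited TPM values, which the authors' run of Salmon scaled to transcript length and to the same sum in every library, were not tested. Whether strand was used in counting is not given in the sources used here.

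Transcripts were summed to genes. The reference annotation at hand was GENCODE M21 on GRCm38, an older build than the authors' GRCm39, so it served only to match transcript identifiers, with the version dropped, to genes, symbols and gene types, and no coordinates are given. It matched 92.72% of the transcripts, which held 88.77 to 98.17% of the reads of a library; the remaining 1.835 to 11.23% of reads entered no test. Gene sums were rounded to whole numbers. The files held 12.49 to 29.68 M reads per library. Near-identical copies (Hba-a1 and Hba-a2, H2-Q6 and H2-Q7, the histone cluster genes) and genes that overlap another gene (Asdurf, Chtf8, Rsc1a1) share reads that the estimate had to divide, so their single values are uncertain. Mitochondrial genes have nuclear copies, and 16 such copies were found by matching sequences.

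Groups and replicate numbers came from the sample titles. Nothing in the sources used here states that each biopsy came from a separate animal, so p-values measure the spread between these samples. No pair of libraries within a group agreed within sampling noise: the lowest chi-square per gene of any pair was 8.631. The comparisons were anti-PD-L1 without ABX, ABX under anti-PD-L1, EXL01 under ABX and anti-PD-L1, and EXL01 with ABX against the ABX-free group, both under anti-PD-L1. The main tests, the 26 gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

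Genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on all 42 libraries with group as the only factor, after filterByExpr with its minimum count of 10 and TMM normalization. This left 16368 genes. P-values were two-sided and adjusted with the Benjamini-Hochberg method, with a threshold of 0.05 and no minimum fold. Fold changes are given on the log2 scale with their standard error (SE), and levels as CPM with the SD between libraries. The named genes were, per comparison, the 10 with the largest rise and the 10 with the largest fall among genes past the threshold with a mean of at least 1 CPM and an established symbol. Named in every comparison were also Cd274, Pdcd1, Cd8a, Ifng, Gzmb, Prf1, Foxp3, Cxcl9, Il10 and H2-Ab1, and for each list described up to 4 members with the smallest p. Some genes that these rules name are not reported here.

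The 26 lists held markers of T cells, cytotoxic effectors, NK cells, T cell checkpoints, regulatory T cells, B and plasma cells, macrophages, neutrophils and dendritic cells. They also held interferon-gamma response, type I interferon response, MHC class I, MHC class II, cytokine and chemokine, proliferation, hypoxia and glycolysis genes, and extracellular matrix and fibroblast and endothelial markers. Markers of other tissue that a biopsy could hold (skeletal muscle, adipocyte, keratinocyte, epithelial, melanocyte, erythroid) and genes that bear on handling and RNA quality (immediate early and stress, mitochondrially encoded) completed them. A list's score in a library was the mean log2 CPM (prior count 2) of its tested members. Scores were compared by a two-sided permutation test of the difference of means, exact where a group had under 10 libraries and otherwise with 100000 resamples, and adjusted over the 26 lists of a comparison. The permutation test takes the library as its unit, so correlation between the genes of a list does not inflate it. A larger spread in the smaller group can still inflate it. The test of camera (limma 3.58.1) was run beside it, with a preset correlation of 0.01 and with an estimated correlation. Camera asks whether a list differs more than the other genes, and with an estimated correlation it called no list in any comparison.

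Library measures were the depth, the shares of reads in mitochondrial genes and in 7S RNA (Rn7s1 and Rn7s2), the share of protein-coding-gene reads that fell in transcripts annotated as retained introns, the share in gene models that lie within introns, and the length minus the effective length of long transcripts, which follows the fragment length. On simulated counts made from these libraries, 16193 genes were tested for anti-PD-L1 without ABX, and 62.69% of genes changed 1.5-fold, 76.12% of those changed 2-fold and 98.48% of those changed 4-fold were recovered. The same shares were 68.66%, 92.54% and 100% for ABX under anti-PD-L1 (16178 genes), 64.18%, 94.03% and 98.48% for EXL01 under ABX and anti-PD-L1 (16176 genes), and 65.67%, 89.55% and 100% for the comparison of EXL01 with the ABX-free group (16193 genes). Of the gene calls 4.142%, 6.383%, 3.333% and 4.945% were false in that order, and 0 of 22, 0 of 22, 2 of 21 and 0 of 20 unchanged lists were called. Each gene was drawn on its own in these counts. The false shares therefore do not cover differences that many genes of a library have in common, such as that in retained introns.

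Alternatives chosen before the data were examined were DESeq2 size factors, DESeq2 1.42.0, limma-voom with quality weights, no filter, an offset for transcript length, a fit of only the 2 groups compared, a block for the replicate number, 6 surrogate variables (sva 3.50.0), leaving out each library in turn, and for lists the median of members, the mean z score, a prior count of 0.5 and camera. Alternatives chosen after seeing the data were the retained-intron share as a covariate, depth as a covariate, leaving out the 5 libraries in which 7S RNA took over 10% of gene reads, and testing protein-coding genes only.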

Results

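The series profiled the RNA of 42 mouse tumour biopsies collected on day 13 after inoculation, to examine at the tumour level what EXL01, a strain of the gut bacterium Faecalibacterium prausnitzii, does under an antibody against PD-L1, the ligand of the T cell receptor PD-1. The labels give 4 groups. These are ABX-free mice on vehicle (n = 10), ABX-free mice on anti-PD-L1 and vehicle (n = 6), ABX mice on anti-PD-L1 and vehicle (n = 14), and ABX mice on anti-PD-L1 and EXL01 (n = 12). Depth ran from 12.49 to 29.68 M reads per library, with means of 22.66 ± 3.503, 19.57 ± 3.065, 22.93 ± 2.509 and 20.14 ± 3.801 M reads (SD) in that order. After filtering, 16368 genes were tested in each comparison.

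A property of the RNA differed between the groups. Transcripts annotated as retained introns took 5.20 ± 0.947% (SD, n = 10) of protein-coding-gene reads in the ABX-free vehicle group and 7.13 ± 1.40% (n = 6) in the ABX-free anti-PD-L1 group. The share was 5.18 ± 0.602% (n = 14) in the ABX anti-PD-L1 vehicle group and 6.66 ± 1.30% (n = 12) in the EXL01 group. Permutation tests gave p = 0.00562 for anti-PD-L1 without ABX, 0.000413 for ABX under anti-PD-L1, 0.00106 for EXL01 under ABX and anti-PD-L1 and 0.4928 for EXL01 with ABX against the ABX-free group (adjusted over 6 library measures: 0.0337, 0.00098, 0.00159 and 0.844). The difference between transcript length and effective length, which follows the fragment length, moved the opposite way. It was 221.9 ± 18.8, 201.7 ± 13.3, 225.4 ± 8.17 and 210.7 ± 11.1 bases (SD). Its permutation p was 0.0366, 0.000129, 0.00066 and 0.15 in the same order of comparisons (adjusted 0.0732, 0.000774, 0.00132 and 0.45). The share in gene models within introns moved with the retained-intron share (permutation p = 0.023, 0.00049, 0.00014 and 0.659). Neither measure was used as a covariate. The retained-intron shares stand beside each comparison because the gene calls moved with them.

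The comparison of anti-PD-L1 with vehicle in ABX-free mice asks what the antibody changed in tumours without ABX. Some genes of T cells and myeloid cells were higher with the antibody, while others, Gzmb, Prf1, Foxp3 and Il10 among them, did not pass. Cd274, which encodes PD-L1 itself, rose from 57.0 ± 15.4 (SD, n = 10) to 110 ± 26.1 CPM (SD, n = 6), a log2 fold change of 0.95 ± 0.19 (SE, adjusted p = 0.0015). Pdcd1lg2, which encodes the other PD-1 ligand, PD-L2, rose from 0.635 ± 0.537 to 4.01 ± 2.44 CPM, a log2 fold change of 2.62 ± 0.46 (adjusted p = 0.000656), and was above the vehicle median in 6 of 6 libraries. Cd4, the co-receptor of helper T cells, rose by 2.15 ± 0.42 on the log2 scale (adjusted p = 0.00133). Arg1, the arginase of alternatively activated myeloid cells, rose from 148 ± 29.6 to 327 ± 58.2 CPM (log2 1.14 ± 0.21).

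The T cell checkpoint list, receptors and ligands that restrain T cells, had a score higher by 0.97 on the log2 scale (exact permutation test, adjusted p = 0.0211). Of its 12 members 10 rose and 2 did not pass (11 higher adjusted over the list alone), among them Vsir (log2 0.90 ± 0.22), Entpd1, the ectonucleotidase CD39 (log2 1.07 ± 0.26), and Pdcd1, which encodes PD-1 (log2 1.24 ± 0.35, adjusted p = 0.0121). The macrophage score was higher by 0.66 (exact permutation test, adjusted p = 0.0249). Of its 16 members 9 rose and 7 did not pass (12 higher adjusted over the list alone), with Mertk, a receptor for dying cells, at log2 1.10 ± 0.25, the mannose receptor Mrc1 at 1.05 ± 0.25 and Cd68 at 0.69 ± 0.19. The neutrophil score was higher by 1.04 (exact permutation test, adjusted p = 0.013). The score rests on 9 of the list's 14 members, since Ly6g, Retnlg, Camp, Ngp and Ltf were not among the genes tested. Of its 9 tested members 4 rose and 5 did not pass (6 higher and 1 lower adjusted over the list alone), namely the growth factor receptor Csf3r (log2 1.89 ± 0.35), the chemokine receptor Cxcr2 (2.30 ± 0.61), Clec4d (1.27 ± 0.33) and the alarmin S100a8 (1.96 ± 0.61). By camera with an estimated correlation, which called no list in any comparison, the adjusted p was 0.579 for each of these 3 lists. With the retained-intron share as a covariate none passed (adjusted p = 0.207, 0.207 and 0.433). The SD of these scores was 0.81, 0.55 and 0.36 with the antibody (n = 6) against 0.30, 0.29 and 0.43 on vehicle (n = 10). The checkpoint and macrophage scores thus had the larger spread in the smaller group.

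Other immune lists missed the threshold as scores with all libraries, although single members passed. The T cell score was higher by 0.90 (exact permutation test, adjusted p = 0.0825), and 15 of 18 members rose (17 adjusted over the list alone). They included Ubash3a (log2 1.91 ± 0.40), Cd5 (1.95 ± 0.47) and the co-stimulator Cd28 (1.37 ± 0.34). The interferon-gamma response score was higher by 0.37 (exact permutation test, adjusted p = 0.0825), with 7 of 22 members higher (7 adjusted over the list alone). Nlrc5 and Ciita, the transactivators of MHC class I and class II genes, rose by 0.68 ± 0.10 and 1.53 ± 0.31 on the log2 scale, the guanylate-binding protein gene Gbp4 by 1.03 ± 0.21 and the T cell attractant Cxcl9 by 0.84 ± 0.22 (adjusted p = 0.00802). The MHC class II score was higher by 0.59 (exact permutation test, adjusted p = 0.11), with 4 of 8 tested members higher (5 adjusted over the list alone): Cd74, the invariant chain (log2 1.45 ± 0.31), H2-Aa (1.34 ± 0.33), H2-Ab1 (1.30 ± 0.32) and H2-Eb1 (1.22 ± 0.32).

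Among cytotoxic genes Cd8a rose by 1.27 ± 0.39 (adjusted p = 0.0192) and Ifng, the gene of interferon gamma, by 1.57 ± 0.39 (adjusted p = 0.00547) on the log2 scale. Granzyme B (Gzmb, log2 0.21 ± 0.22, adjusted p = 0.491) and perforin (Prf1, 0.37 ± 0.27, adjusted p = 0.328) did not pass, nor did Foxp3 (0.82 ± 0.45, adjusted p = 0.185) and Il10 (1.05 ± 0.49, adjusted p = 0.121). Il10 turned to -0.10 without ABX-free anti-PD-L1 replicate 1. The hypoxia and glycolysis score was lower by 0.55 without passing (exact permutation test, adjusted p = 0.11). Of its 16 members 3 fell (4 lower adjusted over the list alone), namely Pdk1, which holds pyruvate back from the mitochondria (log2 -0.50 ± 0.16), the glycolytic enzyme Pgk1 (-0.47 ± 0.16) and Bnip3 (-0.79 ± 0.28). With single libraries left out in turn, the call of Bnip3 ended in 10 of 16 fits, that of Pgk1 in 6 and that of Pdk1 in 3.

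Of the remaining largest rises, Inpp5j, an inositol phosphatase, reached log2 2.68 ± 0.51, Ms4a8a 2.60 ± 0.44, Adgb 2.19 ± 0.43 and the formyl peptide receptor Fpr2 2.05 ± 0.44, while Tnn (tenascin N, 2.69 ± 0.76), Prl2c3 (2.33 ± 0.63) and Tbc1d30 (2.20 ± 0.44) lost their calls without ABX-free anti-PD-L1 replicate 1. The largest falls reported were mostly red cell genes: Hba-a1 (log2 -6.10 ± 1.41), Hba-a2 (-5.453 ± 1.362), Hbb-bs (-5.03 ± 1.26), the anion exchanger Slc4a1 (-3.57 ± 1.08), the haem enzyme Alas2 (-2.85 ± 1.01) and Tent5c (-1.58 ± 0.53). All 5 tested erythroid members were lower (5 adjusted over the list alone), with a score lower by 2.20 (exact permutation test, adjusted p = 0.145). Each of these 6 calls ended without ABX-free vehicle replicate 6, where Hba-a2 stood at 8.78 log2 CPM against a median of 0.66 in the other vehicle libraries. The histone gene Hist1h2br (-4.10 ± 1.29), 1 of the entries for Rmrp, the RNA of RNase MRP (-1.66 ± 0.39), and Omd (-1.63 ± 0.57) also fell.

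In all, edgeR called 3168 genes for anti-PD-L1 without ABX, 1921 higher and 1247 lower, of which 325 of the higher were intronic or unconfirmed gene models out of 1383 tested. Without ABX-free anti-PD-L1 replicate 1 the count was 2044, and the calls of Pdcd1, Cd8a, Ifng, Cxcl9, H2-Ab1, H2-Aa, H2-Eb1, Cd28, Vsir, Entpd1, Clec4d, Tnn, Prl2c3, Tbc1d30, of the lower genes Pdk1, Pgk1, Bnip3, Hist1h2br, Omd and Alas2, and of the T cell checkpoint (adjusted p = 0.0649) and macrophage lists (0.0909) ended. Both lists also ended without replicate 2 or replicate 8 (adjusted p = 0.0563 and 0.0664 in each case), as did Cd68 without replicate 8 and S100a8 without replicate 3. The count was 4774 without replicate 7 and 1905 without replicate 8. Leaving out replicate 7 also made the T cell (adjusted p = 0.00866), interferon-gamma response (0.0397), MHC class II (0.0397) and hypoxia and glycolysis lists (0.0161) pass by the permutation test. The interferon-gamma response list passed without ABX-free vehicle replicate 1 as well (0.019). With the retained-intron share as a covariate 856 genes passed, among them Pdcd1lg2 (log2 1.91, adjusted p = 0.0215), Cd4 (1.60, 0.03), Arg1 (0.96, 0.0239), Nlrc5 (0.44, 0.0124), Ms4a8a, Inpp5j, Adgb and Tbc1d30. The other calls named above for this comparison ended with that covariate. They include Cd274 (0.65, adjusted p = 0.0529), Pdcd1 (0.73, 0.226), Cd8a (0.70, 0.32), Ifng (0.94, 0.164), Cxcl9 (0.73, 0.0809), H2-Ab1 (1.16, 0.0609), Ciita (1.05), Gbp4 (0.67), Mertk (0.76), Mrc1 (0.57) and Csf3r (1.19). The red cell genes lost their calls with most of their folds left, at -4.86 for Hba-a1, -4.57 for Hba-a2, -4.17 for Hbb-bs, -3.09 for Slc4a1, -2.33 for Alas2 and -1.39 for Tent5c.

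**Figure D1:**
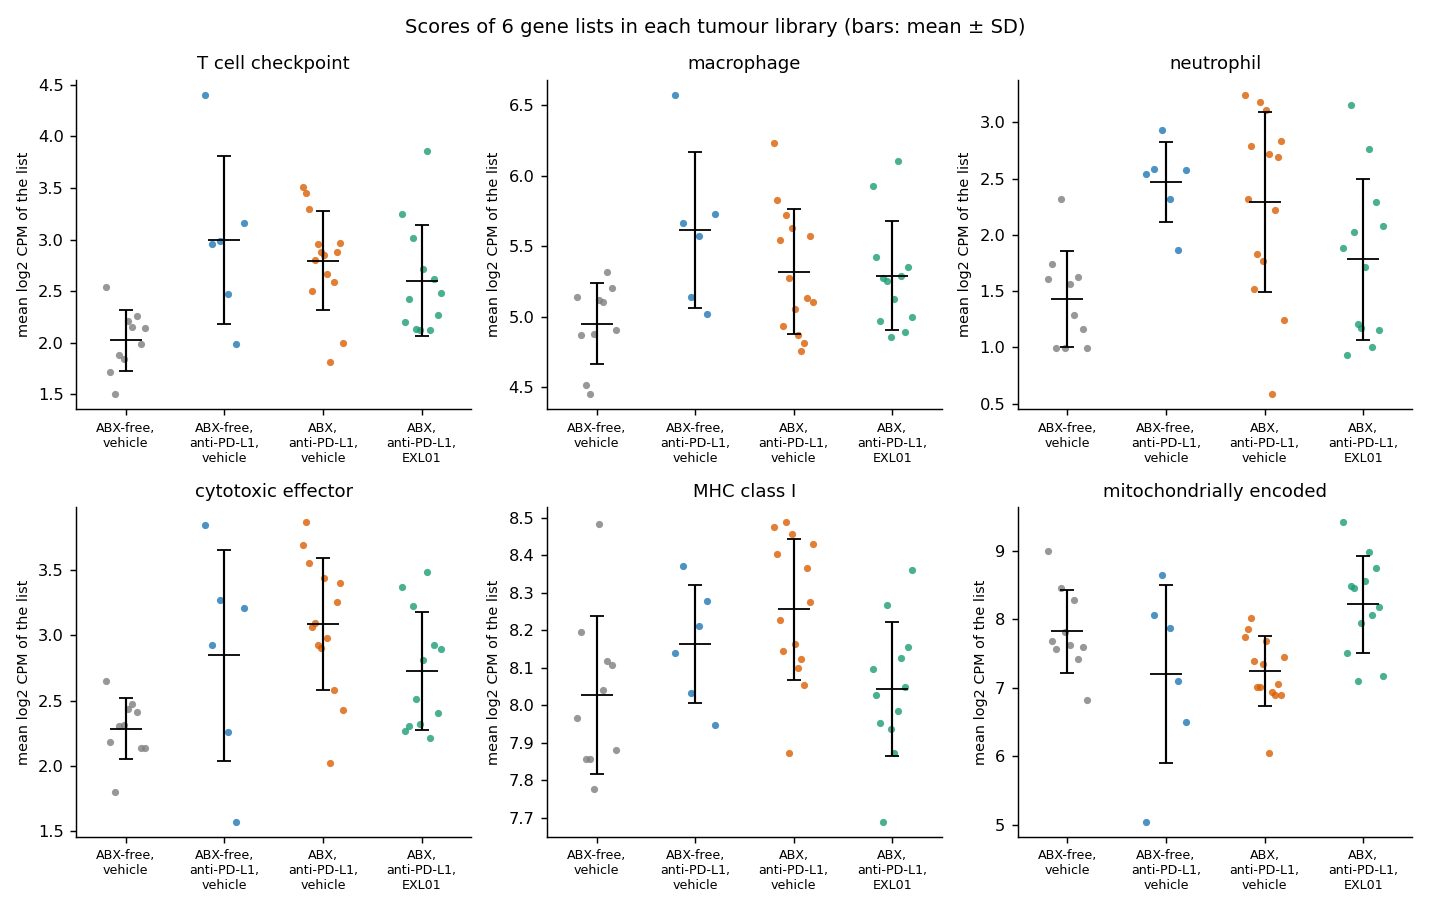
Scores of 6 gene lists (vertical axis, mean log2 CPM) in each of the 42 libraries by group, with the group mean and SD as bars. T cell checkpoint, macrophage and neutrophil scores were higher in the ABX-free anti-PD-L1 group than in the ABX-free vehicle group, and the mitochondrially encoded score was higher with EXL01 than in the ABX vehicle group (8.22 ± 0.707 against 7.24 ± 0.510), each by the permutation test. Camera with an estimated correlation, a test of a list against the other genes, called none of them (adjusted p = 0.579 for the first 3 and 0.955 for the last).

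The second comparison asks how ABX altered tumours of mice given anti-PD-L1. Cd274 was lower with ABX, at 76.5 ± 18.8 (SD, n = 14) against 110 ± 26.1 CPM (SD, n = 6; log2 -0.52 ± 0.18, adjusted p = 0.0365), and lay under the ABX-free median in 14 of 14 libraries. Cxcl9 was lower, at 90.4 ± 26.9 against 142 ± 57.8 CPM (log2 -0.65 ± 0.21, adjusted p = 0.0256). Gzmb went the other way, at 88.8 ± 27.2 against 58.1 ± 17.3 CPM (log2 0.61 ± 0.21, adjusted p = 0.0381), and Prf1 lay just outside the threshold (0.70 ± 0.27, adjusted p = 0.058). Pdcd1 (-0.12 ± 0.33), Cd8a (-0.26 ± 0.36), Ifng (-0.47 ± 0.36), Foxp3 (-0.61 ± 0.42), Il10 (-0.60 ± 0.45) and H2-Ab1 (-0.49 ± 0.31) did not pass. Without ABX-free anti-PD-L1 replicate 1 Pdcd1 turned to 0.32, Cd8a to 0.32, Ifng to 0.29 and Il10 to 0.54. Pdcd1 was also at 0.04 without replicate 8. In the fit with the share as a covariate Pdcd1 was at 0.44, Cd8a at 0.34, Ifng at 0.20, Il10 at 0.02 and Foxp3 at 0.0073. With single libraries left out in turn, the call of Cd274 ended in 10 of 20 fits, that of Gzmb in 5 and that of Cxcl9 in 3. None held with the retained-intron share as a covariate, where Cxcl9 was at -0.54, Cd274 at -0.22 and Gzmb at 0.26.

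No list passed as a score. The proliferation score came closest, higher by 0.17 with ABX (exact permutation test, p = 0.0057, adjusted p = 0.148), and with the median of members it was higher by 0.30 (adjusted p = 0.00537). By camera with an estimated correlation its adjusted p was 0.99. Of its 20 members 6 rose, 1 fell and 13 did not pass (6 higher and 1 lower adjusted over the list alone). The replication helicase genes Mcm5 (log2 0.54 ± 0.11) and Mcm2 (0.29 ± 0.09) and the mitotic kinases Aurka (0.46 ± 0.13) and Cdk1 (0.35 ± 0.10) were the clearest. In the interferon-gamma response list 6 of 22 members fell (6 adjusted over the list alone) with a score lower by 0.16 (exact permutation test, adjusted p = 0.869), among them Gbp4 (-0.69 ± 0.19), Nlrc5 (-0.31 ± 0.09) and Ciita (-0.82 ± 0.29). In the cytotoxic effector list Gzmb and Cst7, which encodes a cystatin of killer cells (0.81 ± 0.30), rose and 13 of 15 members did not pass (0 adjusted over the list alone). The call of Cst7 (adjusted p = 0.04998) ended in 13 of 20 fits with single libraries left out, that of Ciita in 10, those of Nlrc5 and Aurka in 3 and those of Gbp4, Cdk1 and Mcm2 in 2. The cytotoxic effector score differed by 0.24 (exact permutation test, adjusted p = 0.869).

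Among genes with a mean of at least 1 CPM and an established symbol, the rule for naming genes here, the 10 largest rises with ABX included short structured RNAs and histone genes. Hist1h2br rose from 0.977 ± 2.00 to 29.5 ± 19.3 CPM (log2 4.85 ± 1.30), the small nucleolar RNA Snord118 by 2.97 ± 0.68, Rmrp from 75.4 ± 53.6 to 269.7 ± 76.7 CPM (log2 1.84 ± 0.38), Hist2h2aa1 by 1.24 ± 0.40 and Hist1h2ai by 1.06 ± 0.31 on the log2 scale. The calcium channel gene Cacna1i (1.49 ± 0.37), the aldehyde dehydrogenase Aldh3a1 (1.13 ± 0.34), Tm2d3 (1.122 ± 0.2098), Alkbh7 (1.10 ± 0.35) and S100a3 (1.08 ± 0.37) were the others. With single libraries left out in turn, the calls of Hist2h2aa1 and Alkbh7 ended in 4 of 20 fits, that of S100a3 in 5 and that of Aldh3a1 in 1. By the same rule the largest falls were Asdurf (-3.07 ± 0.74), the giant muscle protein gene Neb (-2.27 ± 0.68), Tnn (-2.15 ± 0.68), Slc9a7 (-1.62 ± 0.47), Adgb (-1.56 ± 0.39), the inflammasome sensors Nlrp1b (-1.53 ± 0.38) and Nlrc4 (-1.49 ± 0.37), Tbc1d30 (-1.50 ± 0.39), the interleukin-36 receptor Il1rl2 (-1.45 ± 0.36) and Arl5c (-1.43 ± 0.38). Apart from Asdurf, each of these falls lost its call without ABX-free anti-PD-L1 replicate 1, where Tnn and Slc9a7 then turned positive (highest log2 1.01 and 0.28).

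For ABX under anti-PD-L1 edgeR called 3081 genes, 1172 higher and 1909 lower, and 636 of the lower were intronic or unconfirmed models. With an offset for transcript length the split was 1298 higher and 1347 lower. Leaving out ABX-free anti-PD-L1 replicates 1, 2, 3, 5 and 7 in turn gave 1920, 1573, 2012, 1156 and 5028 genes. Depth was higher with ABX, at 22.93 ± 2.509 against 19.57 ± 3.065 M reads (exact permutation p = 0.0191, adjusted over 6 library measures 0.0287). As a covariate it left 1407 genes, 1397 of them called in the main fit, so a part played by depth was not excluded. With the retained-intron share as a covariate 8 genes passed, 2 higher and 6 lower, and every call named above for this comparison ended. Folds shrank for Nlrc5 (-0.06), Ciita (-0.31), Gbp4 (-0.32), Nlrp1b (-0.34), Neb (-0.99), Hist2h2aa1 (0.42), Alkbh7 (0.37), Mcm5 (0.26), Aurka (0.16), Cdk1 (0.11) and Mcm2 (0.12). At least 80% of the fold was left for Snord118 (2.92), Cacna1i (1.45), Cst7 (0.88), Asdurf (-2.50) and Tnn (-1.78).

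The third comparison is the test of EXL01 itself, in ABX mice on anti-PD-L1. Granzyme B and perforin, the proteins with which cytotoxic lymphocytes kill, were lower at the RNA level with EXL01. Gzmb stood at 57.0 ± 17.03 CPM (SD, n = 12) against 88.8 ± 27.2 (SD, n = 14), a log2 fold change of -0.64 ± 0.17 (adjusted p = 0.00338), and lay below the vehicle median in 12 of 12 libraries. Prf1 stood at 71.4 ± 30.2 against 117 ± 42.8 CPM (log2 -0.71 ± 0.21, adjusted p = 0.00771), below that median in 10 of 12. Klrg1, a receptor of differentiated killer cells, fell by 1.02 on the log2 scale (SE 0.27, adjusted p = 0.00344). In contrast, Cd8a (log2 0.03 ± 0.30), Ifng (-0.07 ± 0.30), Cd274 (0.11 ± 0.15), Pdcd1 (-0.28 ± 0.27), Foxp3 (-0.14 ± 0.35), Cxcl9 (0.18 ± 0.17), Il10 (0.08 ± 0.38) and H2-Ab1 (-0.43 ± 0.25) did not pass. With the share as a covariate Cd274 turned to -0.13, Cd8a to -0.47 and Il10 to -0.44. Without EXL01 replicate 9 Cd8a was at -0.22 and Il10 at -0.32. Over the 26 fits without 1 library Cd8a changed sign in 8, Il10 in 2 and Ifng and Foxp3 in 1 each.

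In the cytotoxic effector list 6 of 15 members fell and 9 did not pass (6 lower adjusted over the list alone), with Cst7 at log2 -0.90 ± 0.24 and granzyme A (Gzma) at -0.79 ± 0.23. Its score was lower by 0.36 without passing (permutation test, adjusted p = 0.37). T cell, NK cell and T cell checkpoint scores differed by -0.18, -0.07 and -0.20 (permutation tests, adjusted p = 0.795, 0.819 and 0.634), and no member of those 3 lists passed in edgeR, adjusted over all genes or over the list alone. With the retained-intron share as a covariate Gzmb was at -0.39 ± 0.18 (adjusted p = 0.217) and Prf1 at -0.65 ± 0.25 (adjusted p = 0.126).

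The score of mitochondrially encoded genes, subunits of the respiratory chain read from the mitochondrial genome, was higher by 0.98 with EXL01 (permutation test, adjusted p = 0.00585). Of its 13 members 10 rose and 3 did not pass (11 higher adjusted over the list alone). Among them mt-Atp8 rose from 42.4 ± 18.8 to 156 ± 127 CPM (log2 1.87 ± 0.36), mt-Nd2 by 1.34 ± 0.26, mt-Nd4l by 1.28 ± 0.41, mt-Nd4 by 1.18 ± 0.21, mt-Nd1 by 1.03 ± 0.19 and mt-Nd5 by 0.97 ± 0.19 on the log2 scale. The immediate early and stress score, genes that respond within minutes to stimulation or handling, was lower by 0.35 (permutation test, adjusted p = 0.00364), with the AP-1 subunits Junb (-0.47 ± 0.16) and Jun (-0.33 ± 0.13) lower, 10 of 12 members not passing and 0 passing adjusted over the list alone. Egr1 (-0.48 ± 0.22) and Ier2 (-0.47 ± 0.23) did not pass. Camera with an estimated correlation called neither list (adjusted p = 0.955 for each). Both lists lost their call with the retained-intron share as a covariate (score differences of 0.73 and -0.21, adjusted p = 0.127 and 0.528).

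Several genes of antigen presentation and several chemokines were lower. In the MHC class I list 5 of 12 members fell and 7 did not pass (7 lower adjusted over the list alone). The peptide transporters Tap1 and Tap2 fell by 0.36 and 0.43 on the log2 scale (SE 0.10 and 0.12), and the heavy chains H2-D1 and H2-K1 by 0.42 and 0.33 (SE 0.12 and 0.10). The MHC class I score was lower by 0.21 (permutation test, p = 0.0075, adjusted p = 0.065), and it passed without the 5 libraries rich in 7S RNA (-0.26, adjusted p = 0.00832) and in 4 of 26 fits without 1 library. It was at -0.09 with the retained-intron share as a covariate (adjusted p = 0.528), and by camera with an estimated correlation its adjusted p was 0.955. In the cytokine and chemokine list 4 of 17 tested members fell and 13 did not pass (4 lower adjusted over the list alone): Tgfb1 (-0.37 ± 0.09), the monocyte attractants Ccl2 (-0.39 ± 0.13) and Ccl7 (-0.50 ± 0.13), and the neutrophil attractant Cxcl1 (-0.72 ± 0.24). Its score was lower by 0.20 (permutation test, adjusted p = 0.278). The chemokines Cxcl3 (-1.365 ± 0.4841, adjusted p = 0.0252) and Ppbp (-1.23 ± 0.42) were among the largest falls. The calls of Tap1, Tap2, H2-D1, H2-K1, Tgfb1, Ccl2, Ccl7, Cxcl1, Cxcl3 and Ppbp ended with that covariate, but their folds behaved differently. Those of Tap1 (-0.17), Tap2 (-0.25), H2-D1 (-0.13), H2-K1 (-0.09), Tgfb1 (-0.24), Ccl2 (-0.22) and Ccl7 (-0.35) shrank, while those of Cxcl1 (-0.77), Cxcl3 (-1.69) and Ppbp (-1.35) did not. In the proliferation list 2 members rose, 8 fell and 10 did not pass (3 higher and 8 lower adjusted over the list alone), with Mki67 at 0.41 ± 0.09 and Mcm5 (-0.49 ± 0.09), Aurka (-0.41 ± 0.11) and Cdc20 (-0.46 ± 0.13) lower; its score differed by -0.07 (permutation test, adjusted p = 0.407). With the median of members that difference was -0.22 (adjusted p = 0.00416), and with the retained-intron share as a covariate it was 0.04. By camera with an estimated correlation the adjusted p of the proliferation list was 0.955.

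The largest rises also held Zfp869 (log2 3.05 ± 1.03), Asdurf (2.95 ± 0.66), 1 of the 2 entries for Chtf8 (1.69 ± 0.50), Rsc1a1 (1.63 ± 0.66), Neb (1.61 ± 0.59), the long noncoding RNA Pvt1 (1.41 ± 0.38, adjusted p = 0.0043), which lies beside Myc, and malate dehydrogenase Mdh1 (1.23 ± 0.30). The other large falls were Snord118 (-1.67 ± 0.47), Lsm4 (-1.05 ± 0.23), Hist2h2aa1 (-1.005 ± 0.3046), Rmrp (-0.93 ± 0.28), Wfdc17 (-0.92 ± 0.26), thymidine phosphorylase Tymp (-0.92 ± 0.27) and Hist1h2ai (-0.92 ± 0.24). The call of Rsc1a1 (adjusted p = 0.0479) ended in 20 of 26 fits with single libraries left out, that of Neb in 5 and that of Jun in 6.

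EdgeR called 5958 genes for EXL01 under ABX and anti-PD-L1, 3477 higher and 2481 lower, with a median absolute log2 fold change of 0.36. Of 1383 intronic or unconfirmed models 823 were higher and 0 lower. Alongside, the EXL01 libraries had the higher retained-intron share given above, a mitochondrial share of 1.81 ± 0.357% against 1.33 ± 0.155% of gene reads (permutation test, p = 0.00017) and a lower depth (permutation test, p = 0.0345). With the retained-intron share as a covariate 163 genes passed, 127 higher and 36 lower. Among the calls named above, that of mt-Nd4 (log2 0.98, adjusted p = 0.047) alone did not end. Some genes that lost their call kept at least 80% of their fold, with Snord118 at -1.62, Cst7 at -0.96, Gzma at -0.94, Klrg1 at -0.90, Asdurf at 2.49 and mt-Nd2 at 1.17. Others shrank, with Zfp869 at 1.16, Neb at 0.47, Cdc20 at -0.14, Hist2h2aa1 at -0.33 and Junb at -0.25. In the fit with 6 surrogate variables 889 passed, 383 higher and 506 lower. With an offset for transcript length 3977 passed, 1967 higher and 2010 lower.

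**Figure D2:**
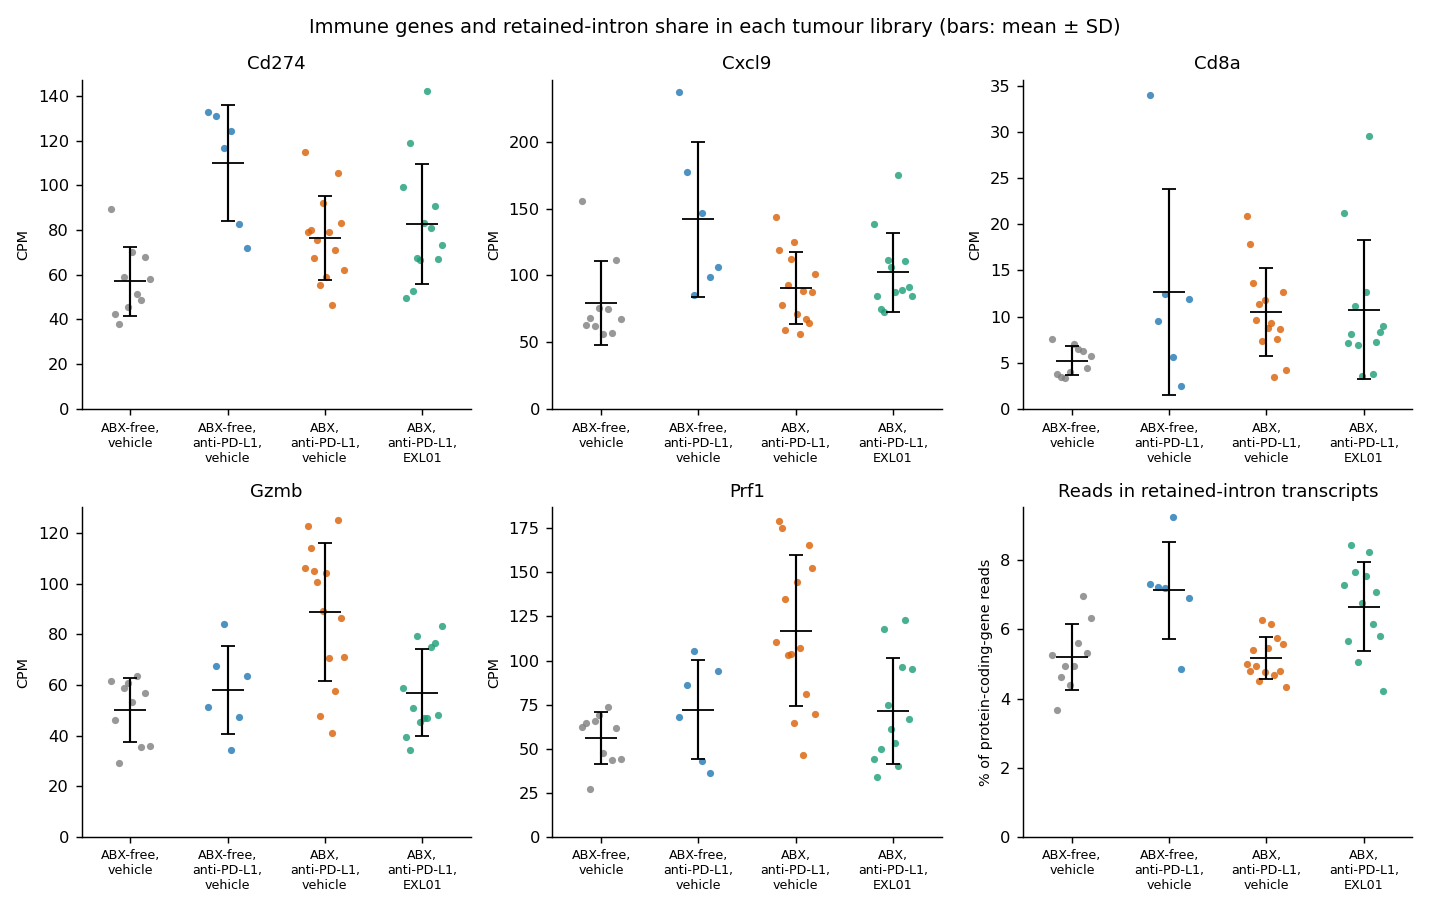
CPM of Cd274, Cxcl9, Cd8a, Gzmb and Prf1, and the share of protein-coding-gene reads in retained-intron transcripts (%), in each library by group, with the group mean and SD as bars. Gzmb averaged 88.8 CPM in the ABX vehicle group and 57.0 CPM with EXL01, and the retained-intron share averaged 5.18% and 6.66% in the same groups.

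The fourth comparison sets the EXL01 group beside the ABX-free group, both on anti-PD-L1. Few genes separated them. Stat3, a transcription factor of cytokine signalling, was lower with EXL01 and ABX at 110 ± 10.5 CPM (SD, n = 12) against 136 ± 11.3 (SD, n = 6; log2 -0.31 ± 0.07, adjusted p = 0.0456), below the ABX-free median in 12 of 12 libraries. Rnf19b, a ubiquitin ligase of killer cells, was lower by log2 -0.51 ± 0.10 (adjusted p = 0.0286). Afap1l2, an actin-associated adaptor, was higher at 6.28 ± 1.2 against 2.92 ± 1.01 CPM (log2 1.10 ± 0.23, adjusted p = 0.0416), as were Dtx4 (0.43 ± 0.08), Ubxn2b (0.57 ± 0.10), Ttc32 (0.73 ± 0.14), the phosphatase Ppm1e (0.61 ± 0.13) and Nanp, of sialic acid synthesis (0.46 ± 0.10). Pou6f1 (-0.77 ± 0.17), Cyth1 (-0.57 ± 0.12), Spata13 (-0.39 ± 0.08) and Tbc1d2b (-0.35 ± 0.08) were lower.

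Gzmb (log2 -0.03 ± 0.21, adjusted p = 0.973) and Prf1 (-0.02 ± 0.26, adjusted p = 0.987) lay close to the ABX-free levels, while H2-Ab1 (-0.92 ± 0.31, adjusted p = 0.176), Cd274 (-0.41 ± 0.18, adjusted p = 0.291), Cxcl9 (-0.47 ± 0.21), Foxp3 (-0.75 ± 0.43), Ifng (-0.54 ± 0.37), Il10 (-0.53 ± 0.47), Pdcd1 (-0.40 ± 0.33) and Cd8a (-0.23 ± 0.37) did not pass. Without ABX-free anti-PD-L1 replicate 1 Il10 turned to 0.62, Cd8a to 0.35, Ifng to 0.22 and Pdcd1 to 0.04. Gzmb and Prf1 also turned in fits without 1 library, to at most 0.11 and 0.12 (without ABX-free replicate 3). In the MHC class II list none of the 8 tested members passed (3 lower adjusted over the list alone), with Cd74 at -0.89 ± 0.30, H2-Eb1 at -0.89 ± 0.31 and H2-Aa at -0.67 ± 0.32. Its score was lower by 0.38 (exact permutation test, adjusted p = 0.474). No list passed as a score (exact permutation tests); with unadjusted p under 0.05 were neutrophil (-0.69, p = 0.045, adjusted p = 0.39), immediate early and stress (-0.31, p = 0.0403, adjusted p = 0.39) and mitochondrially encoded (1.01, p = 0.0402, adjusted p = 0.39).

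EdgeR called 15 genes here, 6 higher and 9 lower, with 2393 at an unadjusted p under 0.05. The retained-intron share did not differ by the test above, and with it as a covariate 135 genes passed, including all 12 named. With single libraries left out in turn, the call of Stat3 ended in 12 of 18 fits, those of Nanp, Pou6f1, Cyth1 and Spata13 in 11 and those of Afap1l2, Ppm1e and Tbc1d2b in 10. The call of Rnf19b ended in 6, those of Ttc32 and Dtx4 in 2 and that of Ubxn2b in 1. The count was unsteady: it was 3, 2, 250, 69, 146 and 0 without ABX-free anti-PD-L1 replicates 1, 2, 3, 5, 7 and 8, and each EXL01 library except replicates 5 and 12 moved it by over 1.5 times when left out, to between 3 and 54; DESeq2 called 157 and limma-voom 0.

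The changes with EXL01 ran opposite to those with ABX. Across the 16368 genes, the EXL01 difference correlated with the ABX difference at Pearson's r = -0.69, with a covariance of -0.115. Part of this arises because the ABX vehicle libraries enter both differences with opposite sign. In 100 reassignments of the EXL01 and vehicle labels among the ABX libraries the median r was -0.20, the lowest -0.62 and the median covariance -0.0114, which left a difference in covariance of -0.103 (permutation p = 0.0099, the smallest these reassignments can give). With separate random sets of ABX vehicle libraries for each difference, so that no library was shared, the median r was -0.58. Both sets came from the same group, so a property of that whole group still entered both differences with opposite sign. With the slope on the retained-intron share removed, r was -0.43, inside the range of the reassignments (median -0.26, lowest -0.45), and the difference in covariance was -0.0263 (permutation p = 0.0099).

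**Figure D3:**
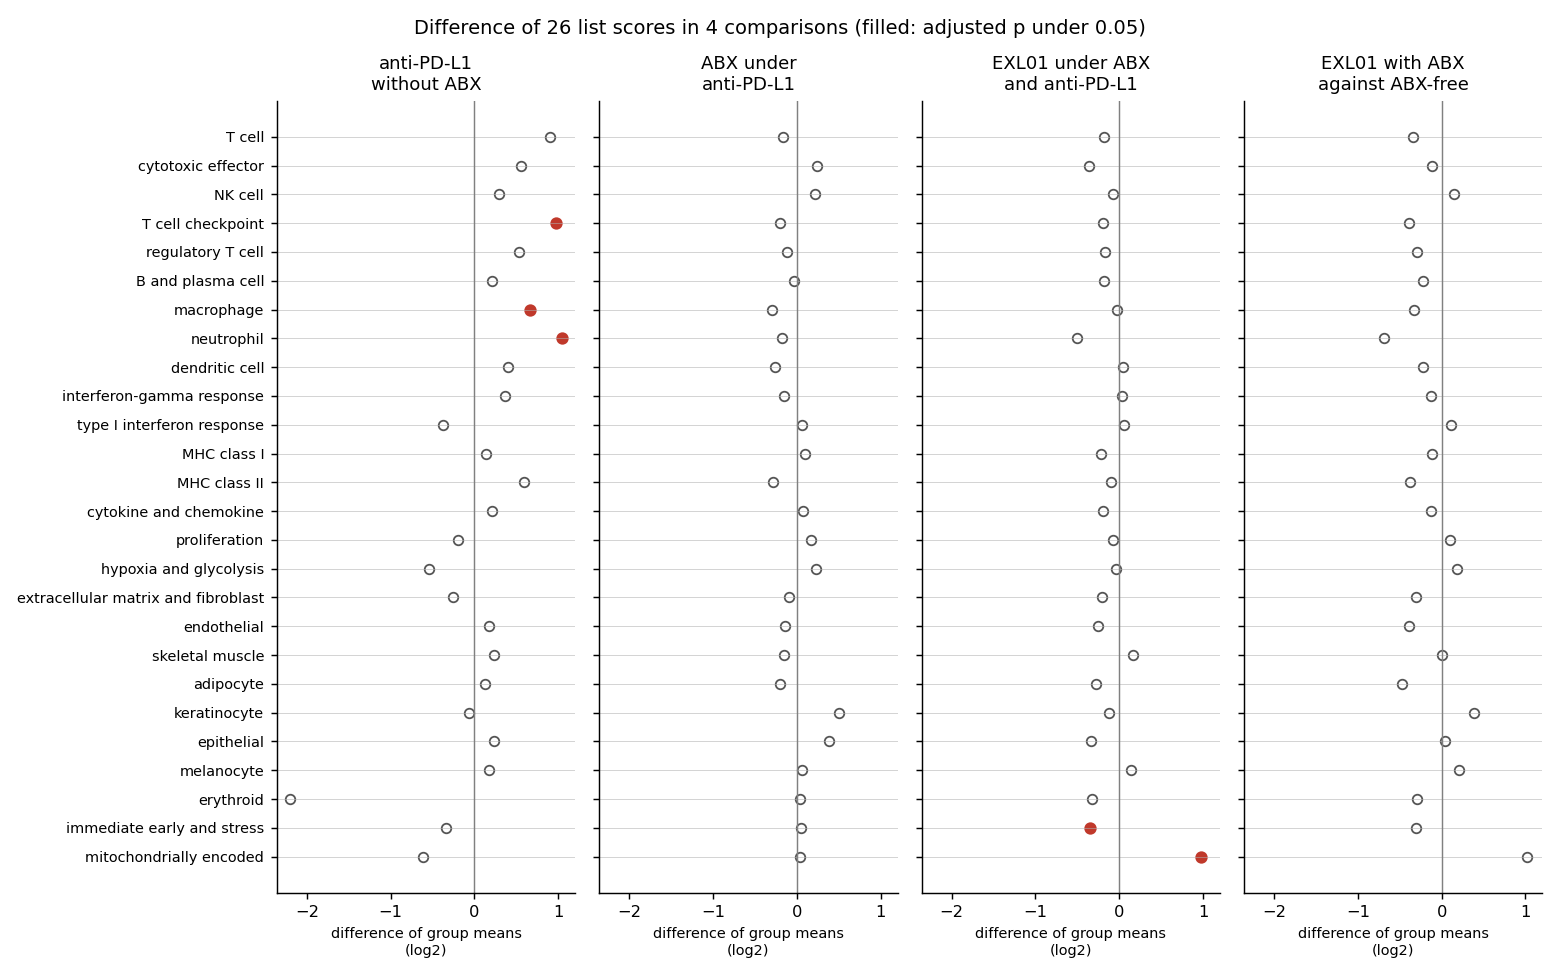
Difference between group means of each of 26 list scores (log2, horizontal axis) in the 4 comparisons, with filled points where the adjusted p was under 0.05. In the panel of anti-PD-L1 without ABX 3 lists passed, in the panel of EXL01 under ABX and anti-PD-L1 2 passed, and in the others none did.

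Lists not yet described missed the threshold. For anti-PD-L1 without ABX (exact permutation tests, adjusted p from 0.11 to 0.747), score differences were 0.56 for cytotoxic effectors (5 of 15 members higher, 8 adjusted over the list alone), 0.30 for NK cells, 0.54 for regulatory T cells, 0.40 for dendritic cells, 0.21 for B and plasma cells, -0.37 for the type I interferon response, 0.14 for MHC class I, 0.21 for cytokines and chemokines, and -0.19 for proliferation. Of the proliferation members 5 of 20 were lower (6 adjusted over the list alone). Extracellular matrix and fibroblast markers gave -0.25 and endothelial markers 0.18. Markers of other tissue gave 0.23 for skeletal muscle, 0.13 for adipocyte, -0.07 for keratinocyte, 0.23 for epithelial and 0.17 for melanocyte genes. Lists that bear on handling and RNA quality gave -0.62 for mitochondrially encoded genes (13 of 13 members not passing) and -0.34 for immediate early and stress genes (3 of 12 members lower). In the comparison of EXL01 with vehicle under ABX, the neutrophil score differed by -0.51, macrophages by -0.03, the interferon-gamma response by 0.03, MHC class II by -0.10, endothelial genes by -0.25, extracellular matrix genes by -0.20, skeletal muscle genes by 0.16 and epithelial genes by -0.34.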

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

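The test of T and NK cell scores was chosen after seeing the data, and so were the retained-intron share and depth as covariates.

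In groups of 4 to 10 libraries, 1 library stood far from the others of its group in 29 of 304 tests, where chance flags about 1 in 20 groups, or 15 tests. Many tested genes were named for their large folds in these same libraries, so 29 against 15 does not measure an excess over chance. The value given is the gap to the nearest other library divided by the range of the group. ABX-free vehicle replicate 6 held 15 of them. It was highest for red cell genes: the erythroid list (0.5013), Hba-a1 (0.5025), Hba-a2 (0.5964) and Hbb-bs (0.5031), and for Tent5c (0.6112). It was also highest for the immediate early and stress list (0.5317), Junb (0.5226), Jun (0.6685), Egr1 (0.5124) and Ier2 (0.6946), for Tap2 (0.4827) and for the share of reads in the 10 highest genes (0.4795). It was lowest for Ubxn2b (0.5572), for the share of reads matched to a gene (0.6418) and for the protein-coding share (0.4927). No explanation was tested for this library.

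ABX-free anti-PD-L1 replicate 1 held 8. It was highest for Tnn (0.651), Prl2c3 (0.6541), Il10 (0.7139), Slc9a7 (0.7694) and the 7S RNA share (0.7268, at 11.39% against 5.748% in the nearest other library), and lowest for the melanocyte list (0.7109), S100a3 (0.66) and mt-Nd4l (0.6446). Single results set apart ABX-free anti-PD-L1 replicate 3 (highest Hist1h2br, 0.631) and 4 ABX-free vehicle libraries. These were replicate 3 (lowest Prf1, 0.481, and lowest in 1 Chtf8 entry, 0.7633), replicate 1 (highest mt-Nd4l, 0.5329), replicate 4 (highest Cxcl3, 0.5353) and replicate 8 (highest Tbc1d2b, 0.5962).

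EdgeR called 5958 genes with EXL01 under ABX and anti-PD-L1, beside a higher retained-intron share. A difference in depth was argued against as the whole cause, because 79.54% of the calls stayed with depth as a covariate. A share of unprocessed RNA in the library may account for much of the pattern. Across genes, the EXL01 fold correlated at 0.5823 with the slope on that share among the 10 ABX-free vehicle libraries, which the comparison does not use (one-sided permutation p = 0.0184), and 135 calls stayed with the share as a covariate, the median absolute log2 fold falling from 0.36 to 0.18 with a median SE of 0.10 in both fits. An effect of EXL01 on RNA processing, or on the cells that make up the biopsy, stays open as untested, since the share itself differs between the groups.

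Gzmb and Prf1 were lower with EXL01, by 0.68 on average on the log2 scale. Fewer T and NK cells cannot be told apart from lower expression per cell, because the mean of the T cell and NK cell scores differed by -0.1223 with a 95% interval from -0.4968 to 0.275, which holds both 0 and the bound set for the test, -0.3381. The retained-intron share also stays open: 76.89% of the change was left with it as a covariate, but neither gene stayed past the threshold as the fold of Gzmb went from -0.64 ± 0.17 to -0.39 ± 0.18 and that of Prf1 from -0.71 ± 0.21 to -0.65 ± 0.25. A direct effect of EXL01 on killer cells was not tested.

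Mitochondrially encoded transcripts were higher with EXL01. Reads moved between the mitochondrial genes as a whole and their 16 nuclear copies were argued against. The summed share differed by 145.4% of the difference of the mitochondrial genes alone (2.396% against 1.699%, permutation p = 3e-05). These shares covered every mitochondrial gene (without the copies 1.808% against 1.329%), not only the 13 members of the list. Reads moved at the list members alone were not tested. The retained-intron share may still contribute: 74.57% of the list difference was left with it as a covariate, at an adjusted permutation p of 0.1265, so the call ended and the question stays open. An effect of EXL01 on mitochondrial content was not tested.

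In 3 comparisons chance was argued against as the source of the gene counts by 100 splits of the libraries each, the real one included. Such splits cannot tell the groups from a library property that differs with them, such as the retained-intron share. For anti-PD-L1 without ABX 1 split gave as many genes as the real 3168 (highest other 1021). The same held for ABX under anti-PD-L1 (1 split, real 3081, highest other 241) and EXL01 under ABX and anti-PD-L1 (1 split, real 5958, highest other 0). For EXL01 with ABX against the ABX-free group 3 splits gave at least the real 15 genes, and 1 of them gave 998, which points to a structure of the samples beyond the groups. The 3 of 100 lie under 0.05, but the count ran from 0 to 250 with single libraries left out and was 0 with limma-voom, so chance stays open there. In the split with 998 genes the retained-intron share differed by 1.554 percentage points, and the cause of its calls was not tested.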

How the results depend on the processing

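The retained-intron share and depth as covariates, leaving out the 5 libraries rich in 7S RNA, protein-coding genes alone and the reversal with the share removed were chosen after seeing the data. DESeq2 size factors left every gene count within 1.5 times its main value and every named gene on its side of the threshold. The reversal's difference in covariance was -0.103, and it was -0.103 with DESeq2 size factors, -0.104 with genes of at least 1 CPM and -0.0263 with the share removed, where the correlation of -0.43 was no longer below the lowest reassigned one of -0.45. The covariance itself, before the reassigned median is taken off, was -0.115 and had a median of -0.103 with no shared ABX vehicle libraries. Unless stated, the cause of a change was not tested.

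For anti-PD-L1 without ABX (3168 genes), 856 passed with the share as a covariate and 1087 with only the 2 groups compared. A fit of only the 2 groups compared did not lower every count. It gave 3332 genes for ABX under anti-PD-L1 and 7053 for EXL01 under ABX and anti-PD-L1. For ABX under anti-PD-L1 (3081), 8 passed with the share, 1407 with depth as a covariate and 5345 with limma-voom. Depth itself differed between the groups of that comparison, so its part in those calls was not excluded. For EXL01 under ABX and anti-PD-L1 (5958), 889 passed with surrogate variables and 163 with the share. For EXL01 with ABX against ABX-free (15), 36 passed with no filter, 31 with a length offset, 40 with surrogate variables, 135 with the share, 5 with depth, 2 without the 7S-rich libraries, 32 among protein-coding genes, 0 with only the 2 groups compared, 0 with limma-voom and 157 with DESeq2.

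The replicate block, which would apply only if the numbers paired libraries, gave 1441, 823 and 2 genes for anti-PD-L1 without ABX, ABX under anti-PD-L1 and EXL01 against ABX-free, and 0 lists for EXL01 under ABX and anti-PD-L1. No pairing by number was detected: the 49 same-number pairs across groups had a median correlation of 0.0138, and 4 of 42 libraries correlated best with their own number. A weak pairing need not show in this check, so it is not excluded.

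Of the fixed lists, 3 passed for anti-PD-L1 without ABX. This became 1 with the median of members, 11 with camera at a preset correlation, 0 with an estimated correlation, 0 with the share and 0 without the 7S-rich libraries. For ABX under anti-PD-L1 it went from 0 to 1 with the median of members (proliferation). For EXL01 under ABX and anti-PD-L1 it went from 2 to 4 with the median of members, 4 with the mean z score, 1 at a preset correlation, 0 with an estimated one and 1 with the share, the neutrophil list, which is neither of the 2. For EXL01 against ABX-free it went from 0 to 11 at a preset correlation.

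Some called genes reversed. For anti-PD-L1 without ABX, Tnn was at -0.50 with surrogate variables and -0.27 without the 7S-rich libraries. For ABX under anti-PD-L1, Tnn was at 0.33, 0.87 and 0.18 with surrogate variables, without those libraries and with limma-voom. Slc9a7 was at 0.26 and 0.20 under the first 2 of these, and Tbc1d30 at 0.0115 with limma-voom. Folds that had not passed also changed sign with the share. For ABX under anti-PD-L1 these were Pdcd1 (0.44), Cd8a (0.34), Ifng (0.20), Il10 (0.02) and Foxp3 (0.0073), and for EXL01 under ABX and anti-PD-L1 they were Cd274 (-0.13), Cd8a (-0.47) and Il10 (-0.44).

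With each library left out in turn, gene counts ran from 1905 to 4774, 1156 to 5028, 5011 to 6866 and 0 to 250 in the order above, and list counts from 1 to 13, 0 to 0, 2 to 3 and 0 to 0. ABX-free anti-PD-L1 replicates moved counts by over 1.5 times: replicates 1 (2044), 7 (4774) and 8 (1905) for anti-PD-L1 without ABX, and 1 (1920), 2 (1573), 3 (2012), 5 (1156) and 7 (5028) for ABX under anti-PD-L1. Without replicates 1, 2, 3, 5, 7 and 8 the count for EXL01 against ABX-free was 3, 2, 250, 69, 146 and 0, and each EXL01 library but replicates 5 and 12 moved it by over 1.5 times.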

Other observations

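The family of histone cluster genes was chosen after values of single members were seen.

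Histone cluster genes, which package new DNA and mostly lack poly(A) tails, were called in 3 comparisons, in each of which the retained-intron share differed the other way. Of 64 tested, edgeR called 37 higher and 0 lower for ABX under anti-PD-L1, 0 higher and 35 lower for EXL01 under ABX and anti-PD-L1, and 0 higher and 8 lower for anti-PD-L1 without ABX. Their mean log2 CPM was 6.15 ± 0.338 (SD, n = 10) in the ABX-free vehicle group, 5.73 ± 0.312 (n = 6) in the ABX-free anti-PD-L1 group, 6.38 ± 0.183 (n = 14) in the ABX vehicle group and 5.95 ± 0.398 (n = 12) with EXL01. Differences between these means were 0.65 with ABX (exact permutation p = 0.000206), -0.43 with EXL01 (permutation p = 0.00165) and -0.42 for anti-PD-L1 without ABX (exact permutation p = 0.0279). For EXL01 with ABX against ABX-free edgeR called 0 of them, and the mean differed by 0.22 (exact permutation p = 0.253). EdgeR with the retained-intron share as a covariate called 2 genes of any kind higher for ABX under anti-PD-L1 and 36 lower for EXL01 under ABX and anti-PD-L1, so most of the 37 histone calls with ABX ended. Reads shared among near-identical copies make single members uncertain.

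The main axes of variation took 22.2%, 14.6% and 8.70% of the variance of log2 CPM across the 42 libraries. The share of reads in 16 nuclear copies of mitochondrial genes was higher with EXL01 than in the ABX vehicle group, at 0.588% against 0.371% (permutation p = 1e-05, the smallest these permutations can give).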
